A study of Drosophila melanogaster with 4 samples.

How the data were processed

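Chromatin immunoprecipitation followed by sequencing (ChIP-seq) for the Polycomb group protein Psc was carried out on wild-type Oregon-R embryos of Drosophila melanogaster collected 14 to 16 h into development. Per the labels, the 4 samples were 2 ChIP samples and 2 input samples (fragmented chromatin without immunoprecipitation), each pair numbered 1 and 2, and each input served as the reference for the ChIP list of the same number. Nothing in the labels says whether the replicates came from separate embryo collections, so differences between the 2 ChIP lists measure the spread between these samples, which may be technical.

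The deposited data were 3 lists of enriched regions, called clusters below: 1 for each ChIP sample and 1 combined list for the replicate set. Reads were processed with Bowtie 0.12.7, a short-read aligner, per the submitters' processing notes. Coordinates refer to FlyBase release 5 of the fly genome, per the file headers, and are given 1-based as deposited. The program that called the clusters, its thresholds, the treatment of fragments and reads with several matches, and the way the replicates were combined are not given in the sources used here. The lists hold only regions that passed the submitters' threshold, so a region missing from a list was below that threshold or not testable, and its signal is unknown.

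Each cluster carries a score made by the authors, which was read here as log2 enrichment of ChIP over input; the deposited lists name no unit. The log2 reading rests on the values. Among the 60 highest scores of the combined list, 1507 of the 1770 pairwise differences were the log of a fraction with a denominator of at most 40 on base 2 (tolerance 1e-09), against 94 on the natural base and 141 on base 10. The same count in the replicate lists was 40 and 22 of 1770 on base 2. Since the scaling of the libraries is not stated, scores were used to describe, rank and filter clusters within a list and were not converted to folds. The number of reads behind a cluster is unknown, so no error could be attached to a single score. The inputs have no values of their own here.

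The lists were compared by position. A cluster counted as shared when at least 1 bp overlapped a cluster of the other list. Counts were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and were checked against bedtools 2.31.1, which gave equal counts. Observed overlap was set against 1000 circular shifts of one list along each chromosome, which keep the spacing and widths of the clusters, with a one-sided permutation p whose smallest value is 0.001. Shared length was given as base pairs covered by both lists over base pairs covered by either. Regions paired between the replicate lists were those in which each cluster was the partner with the longest overlap of the other. Spearman and Pearson correlations across these pairs were tested with 100000 permutations, two-sided, with a smallest p of 1e-05. Clusters within 10 kb of each other were joined into domains and compared with 1000 random placements of the same clusters on the same chromosomes, one-sided. The distribution over the arms and chromosome 4 was compared with sequence length by a chi-square test. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Benjamini-Hochberg adjustment was made within each family of tests. Figures were drawn with matplotlib 3.10.9.

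The comparisons of whole lists, their tests and most of the alternative settings were chosen before the data were examined. The alternatives were a required overlap of 50% (reciprocal, or of the cluster itself), the upper score-ranked part of each list, lists of equal length, merging of clusters within 1000 bp, the major arms 2L, 2R, 3L, 3R and X alone, domain gaps of 5 kb and 25 kb, and each replicate list alone. The named items were to be genes if an annotation of the same genome release was at hand. The gene table used here is of release 6 and the lists are of release 5, so no gene was assigned to any region. The tests that need genes, which were the distribution over promoters, exons and introns, the enrichment of gene lists fixed beforehand, and the count of bound genes, were not run. By the rule fixed for that case, the regions named by coordinates are the 10 regions of both replicate lists whose lower percentile by score was highest, and the 10 longest domains of the combined list. Other regions named in the text were chosen after their values were seen: the widest clusters, the clusters nearest to chromosome ends and the highest-scoring unshared clusters.

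The overlap and grouping tests were tested on simulated data. In a simulated list holding exact copies of 48.8% of the 2575 replicate 1 clusters of the major arms plus randomly placed clusters, the measured overlap was 52.6% of those clusters. Among 20 unrelated simulated lists, 1 had a permutation p under 0.05 in the overlap test. Among 20 randomly placed lists, 0 did so in the grouping test. These lists were placed by the same rule as the random placements of that test, so this checks false calls only. The unrelated lists were placed at random too, without the grouping of the real lists, and no grouped list was simulated.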

Results

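Psc is a core subunit of Polycomb repressive complex 1, which binds and keeps silent developmental genes in the fly. The series mapped where Psc sits on chromatin in wild-type embryos late in embryogenesis, 14 to 16 h into development, from 2 ChIP samples, each set against its own input. The replicate 1 list held 2628 clusters covering 6.56 Mb, the replicate 2 list held 2432 clusters covering 5.79 Mb, and the combined list held 8687 clusters covering 17.1 Mb. These clusters took up 5.40%, 4.78% and 14.1% of the major chromosome arms. Most clusters were short: median widths were 1771.5 bp (interquartile range 1469 to 2309) in replicate 1, 1821 bp (1475 to 2360) in replicate 2 and 1449 bp (1140 to 1922.5) in the combined list. The widest clusters reached 93802 bp, 35563 bp and 95591 bp. The authors' log2 enrichment score had a median of 0.57 (interquartile range 0.49 to 0.71) in replicate 1, 0.52 (0.45 to 0.66) in replicate 2 and 0.37 (0.33 to 0.42) in the combined list. Read numbers were not analysed here, so the depth behind each score is unknown.

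The first comparison asked which Psc-bound regions were found in both replicates. Of the replicate 1 clusters, 1351 of 2628 (51.4%, 95% interval 49.5 to 53.3) overlapped a replicate 2 cluster, and 1427 of 2432 replicate 2 clusters (58.7%, 56.7 to 60.6) overlapped a replicate 1 cluster. The shared regions were wider: in replicate 1 the shared clusters had a median width of 2180 bp and a median score of 0.63, and the 1277 unshared clusters had 1536 bp and 0.54. In replicate 2 the medians were 2154 bp and 0.59 for shared clusters, and 1523 bp and 0.49 for the 1005 unshared ones. Of the widest clusters (quartile 4 by width), 91.5% (89.1 to 93.5) in replicate 1 and 97.0% (95.4 to 98.2) in replicate 2 were shared, against 23.0% (19.9 to 26.4) and 30.0% (26.4 to 33.8) of the narrowest (quartile 1).

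By score, the overlap was highest in the top quartile. In replicate 1, 40.5%, 39.6% and 44.4% of the clusters in quartiles 1, 2 and 3 were shared, and 81.1% (77.9 to 84.0) of those in quartile 4. In replicate 2 the shares were 42.8%, 44.2%, 55.3% and 92.4% (90.0 to 94.4). Circular shifts gave a mean overlap of 8.96% for replicate 1 and 9.80% for replicate 2, with maxima of 15.9% and 19.0%, so the observed overlap was 5.74 and 5.99 times the shift mean. The base pairs covered by both lists, 3719363, were 43.1% of those covered by either, against a shift mean of 2.71% and a maximum of 7.28%. All 3 permutation tests gave the smallest p that 1000 shifts can give, 0.001, which Benjamini-Hochberg adjustment over the 3 tests left at 0.001. The shifts were not split by width, and wide clusters also meet another list by chance more often than narrow ones.

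**Figure D1:**
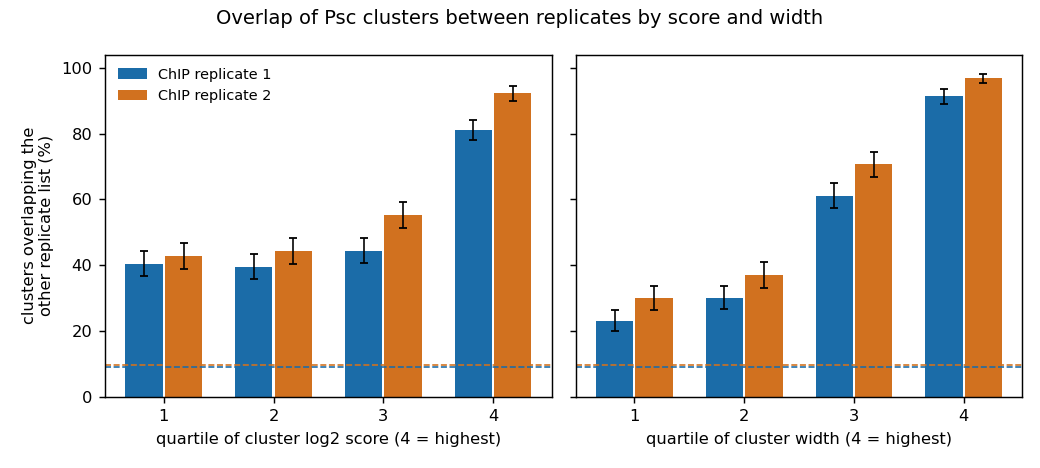
Percentage of Psc clusters of each replicate list that overlapped the other replicate list, by quartile of the authors' log2 score (left) and of cluster width (right); bars are ChIP replicates 1 and 2, error bars are exact 95% intervals, and dashed lines are the mean overlap of all clusters under circular shifts (8.96% and 9.80%). In the widest quartile 91.5% and 97.0% of the clusters overlapped, and in the narrowest 23.0% and 30.0%.

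Among the regions found in both replicate lists, scores and widths rose together. Across these 1294 region pairs, the scores had a Spearman rho of 0.80 and a Pearson r of 0.91, and the log2 widths had a rho of 0.74 and an r of 0.82. Each of these 4 permutation tests gave p = 1e-05, the smallest that 100000 permutations can give, and the adjusted value was 1e-05 as well. The correlations are across regions of 2 samples, and regions are not independent replicates. They leave out the unshared clusters, among them 124 of the 657 replicate 1 clusters and 46 of the 608 replicate 2 clusters in the highest quartile by score.

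**Figure D2:**
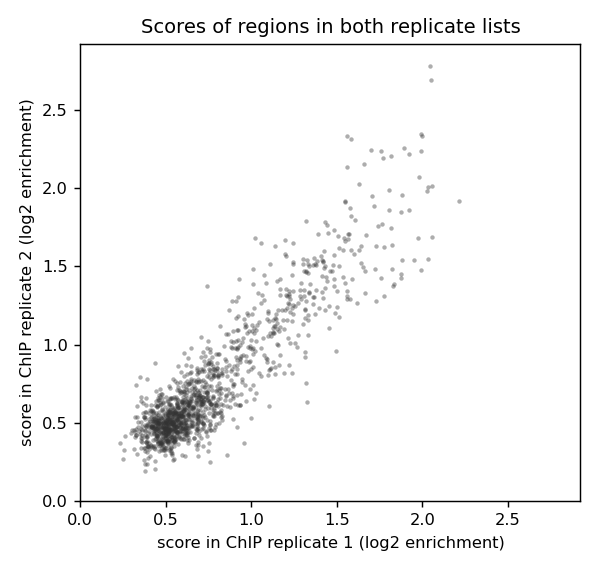
Authors' log2 enrichment score of the 1294 region pairs found in both ChIP lists, replicate 1 on the horizontal and replicate 2 on the vertical axis; each point is a region. Most points lie at low scores in both lists, and the spread follows a rising band (Spearman rho 0.80).

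The 10 regions ranked highest in both lists had scores of 1.89 to 2.06 in replicate 1 and 2.01 to 2.78 in replicate 2. Of these, 5 lay on the X, 2 on 3R and 1 each on 2L, 2R and 3L. The first by rank was the X region 5452055 to 5456455, with scores of 2.05 in replicate 1 and 2.70 in replicate 2. The second was the X region 17660769 to 17664090, with 2.04 and 2.78, and the third was 3L 12601054 to 12607615, with 2.00 and 2.33. Next came 2L 12616663 to 12619738 (1.99 and 2.24) and X 16040493 to 16046013 (1.99 and 2.35). The sixth, X 2014138 to 2026390 (1.98 and 2.07), lay inside a replicate 1 cluster of 30177 bp, while the replicate 2 cluster there was 12253 bp wide. Region 3R 2566167 to 2569431 (1.92 and 2.22) was followed by 2R 1612653 to 1615958 (2.06 and 2.02). The last were 3R 27892962 to 27899640 (2.03 and 2.01), close to the distal end of the arm, and X 16108737 to 16112891 (1.89 and 2.26). No gene was assigned to these regions because the gene table used is of another genome release.

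The combined list was then set against the replicate lists. It contained nearly all replicate clusters: 2532 of 2628 replicate 1 clusters (96.3%, 95.6 to 97.0) and 2368 of 2432 replicate 2 clusters (97.4%, 96.7 to 98.0) overlapped it. All 1351 shared clusters of replicate 1 and all 1427 of replicate 2 were in it, as were 1181 (92.5%) and 941 (93.6%) of the unshared ones. Most of the combined list was found in neither replicate list: 5513 of 8687 clusters (63.5%, 62.4 to 64.5), with a median width of 1232 bp and covering 7.42 Mb. Clusters found in both replicate lists numbered 1169 (13.5%, 12.7 to 14.2), had a median width of 3167 bp and covered 5.87 Mb. A further 1128 met the replicate 1 list only and 877 the replicate 2 list only. Within the combined list the median score was 0.51 for clusters in both replicate lists, and 0.36, 0.36 and 0.37 for those in replicate 1 only, replicate 2 only and neither.

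Narrow regions made up much of the remainder. The combined list had clusters from 1001 bp upwards, and both replicate lists began at 1301 bp. Of the 5513 clusters in neither replicate list, 3179 (57.7%) were narrower than 1301 bp. Among the combined clusters of at least that width, the share in both replicate lists was 22.3%, against 13.5% of all. This last comparison was added after the data were seen.

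Psc clusters were spread over every major arm and were most extensive on 3R. In the combined list they covered 16.8% of 3R, 14.8% of 2R, 14.3% of X, 12.4% of 2L, 11.8% of 3L and 9.53% of chromosome 4. The replicate lists had 3R highest as well, at 7.04% and 6.47%, and 3L lowest, at 4.23% and 3.47%. By number, 2R had 79.2 combined clusters per Mb, 3R 77.2, X 73.8, 3L 64.8, 2L 61.0, and chromosome 4 37.0. Observed over expected numbers in the whole combined list ranged from 0.52 on chromosome 4 and 0.86 on 2L to 1.12 on 2R (chi-square 105 with 5 degrees of freedom, p = 4.35e-21). Clusters lie in groups, so they are not independent and this p is too small. In the replicate lists 3R was highest among the major arms, at 1.18 and 1.24 times its expected number, and 2R stood at 1.03 and 1.00. Chromosome 4 had 1.16 times its expected number in replicate 1 (34 clusters) and 0.997 times in replicate 2 (27 clusters). Among the 4344 combined clusters with the higher scores the order of the arms changed: X rose from 1.04 to 1.63 times its expected number. The other chromosomes fell: 2R and 3R, at 1.12 and 1.09 in the whole list, turned to 0.98 and 0.94. For 2L, 3L and chromosome 4 the values went from 0.86, 0.91 and 0.52 to 0.74, 0.78 and 0.47.

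**Figure D3:**
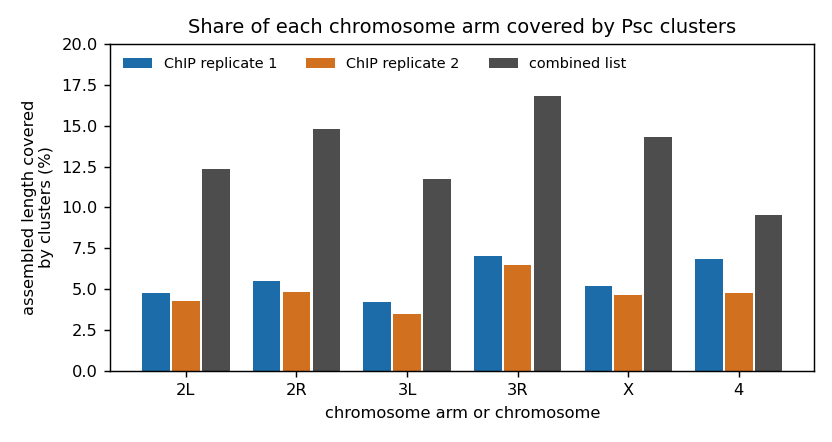
Percentage of the assembled length of each chromosome arm and of chromosome 4 covered by Psc clusters in the replicate 1, replicate 2 and combined lists; each bar is one list without an error. Arm 3R was the most covered in all 3 lists (7.04%, 6.47% and 16.8%).

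The last comparison asked whether Psc clusters lie next to each other. Joined within 10 kb, the 8687 combined clusters formed 3075 domains, of which 1513 held a single cluster and 1562 several. The 442 domains with 5 or more clusters held 4255 clusters (49.0%). Random placement gave 3858 ± 32 domains (SD over 1000 placements), and the largest number of clusters in one domain was 80, against a mean of 16.6 and a maximum of 28 at random (permutation p = 0.001 for both, the smallest possible, and 0.001 after adjustment). The replicate lists alone formed 1406 domains against 2086 at random and 1308 against 1965 (permutation p = 0.001 each). The number of domains depended on the gap. Joined within 25 kb, there were 1276 domains against 1220 at random (permutation p = 0.997, one-sided for fewer domains). The largest domain then still held 100 clusters against a mean of 64.3 at random (permutation p = 0.013).

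Of the 10 longest domains, 5 lay on 3R, the arm that carries the Hox gene complexes of the fly; no gene was assigned to any domain here. The longest spanned 405 kb (3R 2467922 to 2873204) and joined 80 combined clusters, and replicate clusters covered 47.6% ± 3.9 of it (mean and SD, n = 2). The next, 334 kb on 3R (12483932 to 12817919), was the most filled: 93.4% was covered in the combined list and 70.1% ± 4.2 in the replicates (SD, n = 2). It held 47 clusters in replicate 1, 45 in replicate 2 and 27 in the combined list, among them a single combined cluster of 76496 bp. On the X, a domain of 273 kb (8451871 to 8724693) was covered to 31.8% ± 2.2 (SD, n = 2) in the replicates. A further domain of 264 kb on 3R (17198326 to 17461914) was covered to 48.8% ± 2.3, and one of 243 kb on 2R (8757532 to 9000611) to 53.3% ± 5.4 (SD, n = 2 for both). That 2R domain contained the widest cluster of each list. The combined cluster there spanned 95591 bp (8835792 to 8931382, score 1.58), of which replicate 1 covered 99.6% with 2 clusters and replicate 2 covered 92.8% with 5.

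In the other 5 domains, replicate clusters covered 29.8% ± 0.88 of the 228 kb domain on 2L (18720946 to 18948588) and 23.6% ± 6.5 of the 226 kb domain on 3R (6294408 to 6520282). They covered 15.6% ± 1.1 of the 188 kb domain on 3L (6769838 to 6958280) and 38.3% of the 181 kb domain on 3R (7025058 to 7205790) in both replicates. The 177 kb domain on X (4248820 to 4425322) was covered to 37.4% ± 2.5 (SD, n = 2 for each). The replicates differed most in the 226 kb domain on 3R, with 28.2% in replicate 1 and 19.0% in replicate 2. The difference in coverage between the 334 kb domain of 3R and the 188 kb domain of 3L was larger than the spread between replicates of either, and was not tested.

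**Figure D4:**
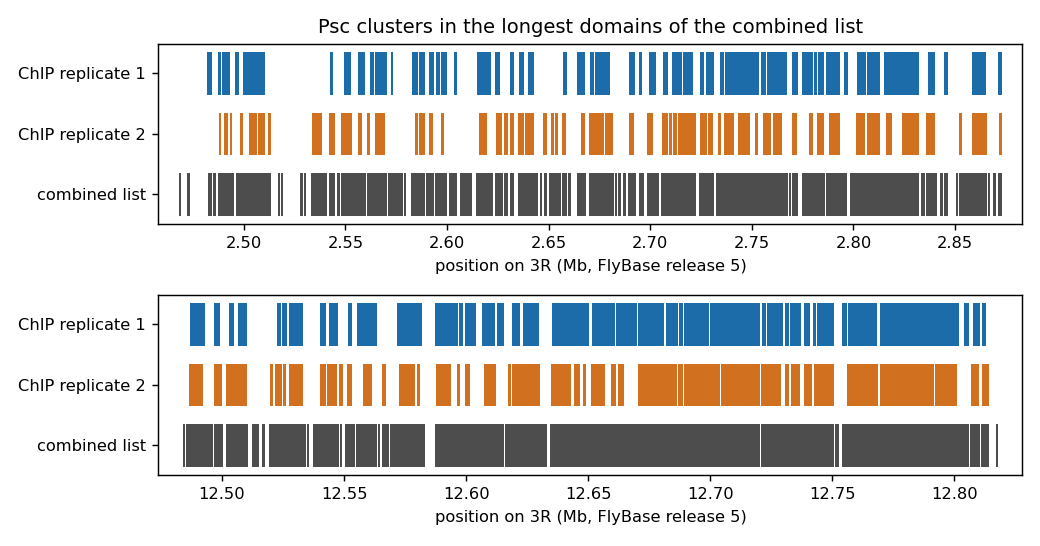
Map of Psc clusters in the longest domains of the combined list, 405 kb (top) and 334 kb (bottom), both on 3R; the horizontal axis is the position in Mb in FlyBase release 5 and each block is a cluster drawn to scale, by list. In the lower domain the combined list covered 93.4% of the length and the replicates 73.1% and 67.1%.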

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

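Of 29 alternatives to 7 results, 24 kept the direction and the side of the threshold or stayed within the allowed spread. Among the 24, those for the distribution over chromosomes were judged by the chi-square p alone, which says nothing of the order of the arms. The alternatives on the major arms for domains and for the combined list, and that on cluster width in the combined list, were chosen after seeing the data. The overlap of the replicates stayed above the shifts under every alternative run, at 43.1% to 53.7% of replicate 1 and 46.6% to 62.0% of replicate 2 clusters, and the rank correlation of scores across regions was 0.80, or 0.85 in the upper score-ranked part of each list; cluster width, another quantity, gave 0.74. The share of combined clusters found in both replicate lists moved from 13.5% to 11.1% when 50% of the cluster itself had to overlap, a stricter demand by construction, and to 22.3% among clusters at least as wide as the narrowest replicate cluster, which leaves out narrow clusters. At a gap of 25 kb the number of domains turned above random, 1276 against 1220 (permutation p = 0.997, one-sided for fewer domains). Random placement kept the number and widths of the clusters, so short gaps within groups leave longer gaps elsewhere. A number above random at a wide gap therefore does not speak against grouping. Whether this accounts for the whole excess was not tested. The largest domain still held 100 clusters against a random mean of 64.3 (permutation p = 0.013), so the reversal was in the number of domains only. With each replicate list alone, 1308 to 1406 domains formed from lists that hold fewer clusters. The order of the arms depended on the list, and the cause was not tested. By number, 2R was highest in the combined list. In replicate 1 it was 3R (1.18 times its expected number, 2R 1.03), as in replicate 2 (1.24, 2R 1.00). In the upper score-ranked part of the combined list the X had 1.63 times its expected number of clusters, against 1.04 in the whole list. There 2R and 3R fell below expectation (0.98 and 0.94, against 1.12 and 1.09), and 2L, 3L and chromosome 4 fell further. That cut, at the list median of 0.374, lay below the 25th percentile of the X scores (0.378) and above the autosomal median (0.363). It therefore kept a larger part of the X clusters than of the autosomal ones. Why the X scores were higher was not tested. No paired analysis was possible because the inputs have no values of their own here, each ChIP list having been made against the input of the same number. The alternatives for the annotation distribution, the gene list enrichment and the bound gene count were not run, since the gene table used is of another genome release. Unknown read numbers limit all scores.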

Other observations

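The regions named here were picked after the lists were seen, and the tests of the smaller minimum width, of clusters split by width or of like width, and of the X scores were chosen only after the result was seen. The outermost Psc cluster lay closer to the distal end of the assembled arm on 3R and 2L than on 2R, 3L, X and chromosome 4. At the distal end of 3R the outermost cluster lay 5.40 kb from the end of the assembled arm in replicate 1 and 5.41 kb in replicate 2, and it was among the strongest of each list, with scores of 2.03 and 2.01 (higher than 99.5% and 99.0% of the clusters). At the distal end of 2L the outermost cluster lay 5.06 kb and 5.05 kb from the end, with scores of 1.33 and 1.19 (above 94.6% and 91.0% of clusters). On 2R the outermost clusters were 13.5 kb and 22.7 kb from the end and weak, with scores of 0.41 and 0.44. On 3L the outermost clusters lay 137 kb and 124 kb from the end (scores 0.53 and 0.49) and on X 139 kb in both lists (0.40 and 0.49). On chromosome 4 they lay 227 kb and 232 kb away, with scores of 0.40 in replicate 1 and 1.55 in replicate 2, the latter above 96.5% of its list. The distances were not compared with chance.

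Clusters on the X had higher scores than clusters on the autosomal arms of the same list. In replicate 1 the median was 0.66 on X (511 clusters) and 0.55 on the autosomes (2064 clusters), a difference of 0.11 (95% interval 0.09 to 0.13 from 1000 bootstraps of 1 Mb blocks). In replicate 2 it was 0.60 against 0.51, a difference of 0.10 (0.07 to 0.11), and in the combined list 0.43 against 0.36, a difference of 0.07 (0.06 to 0.07). The weakest called clusters were higher on X as well. At the 5th percentile the difference was 0.07 (0.04 to 0.09) in replicate 1, 0.06 (0.03 to 0.09) in replicate 2 and 0.05 (0.04 to 0.06) in the combined list. At the 95th percentile the difference was 0.03 (-0.11 to 0.19) in replicate 1, 0.06 (-0.16 to 0.28) in replicate 2 and 0.10 (0.01 to 0.19) in the combined list. The cause of the higher X scores was not tested, so they are not a measure of stronger Psc binding there.

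Some high-scoring but narrow clusters in either replicate list were missing from the other. The highest-scoring of replicate 2 on the arms was 2L 22387946 to 22389269, with a score of 1.98, and the nearest replicate 1 cluster was 240602 bp away. The next was 2R 417832 to 419229 (score 1.28), with the nearest replicate 1 cluster 1176689 bp away. In replicate 1 the highest was 2R 2385933 to 2387253 (score 1.23), 1069 bp from a replicate 2 cluster. Next were X 20462900 to 20464283 (score 1.19), 7286 bp from one, and X 10500900 to 10502529 (score 1.18), 58971 bp from one. All were narrower than the median cluster of their list. In the order above, the widths were 1324 and 1398 bp in replicate 2, and 1321, 1384 and 1630 bp in replicate 1. Each of these 5 regions overlapped 1 combined cluster. The combined scores there were 1.33 and 0.66 for the replicate 2 regions, and 1.32, 0.75 and 0.62 for the replicate 1 regions.

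Most combined clusters, 5513 of 8687, were outside both replicate lists. Of the 5249 combined clusters at least 1301 bp wide, 2334 (44.5%, 43.1 to 45.8) were still outside both, with a median width of 1563 bp. A region can be narrower in a single replicate than in the combined list. This share therefore cannot decide how far the smaller minimum width of the combined list was the cause. Of all 5513, 22.2% were within 10 kb of a region found in both replicate lists. The shifts gave a mean of 16.9% and a maximum of 19.8% (permutation p = 0.001, the smallest possible). The shifts ran over the whole assembled chromosomes and took no account of which sequence can yield calls. They therefore cannot exclude calls unrelated to Psc in such sequence. The excess was larger for the clusters of at least 1301 bp (25.6% against 17.2%) than for the narrower ones (19.8% against 16.6%); the difference between these was not tested. It stays open whether weak Psc binding that passed the threshold only after the replicates were combined may account for clusters outside both lists. That would need the reads, and no biological explanation was tested.

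Clusters on unplaced and heterochromatic sequence, many of them with high scores (medians 1.78 in replicate 1 and 0.96 in replicate 2), were rarely found again. In replicate 1, 2 of all 19 such clusters (10.5%, 1.30 to 33.1) overlapped replicate 2, against 31 of 31 arm clusters that scored at least the median of the 19 (Fisher's exact test, two-sided, p = 1.74e-11); in replicate 2 it was 2 of all 20 (10.0%, 1.23 to 31.7) against 303 of 305 (p = 2.25e-25, exact), and with the same score limit on both sides it was 0 of 10 (exact p = 8.92e-10) and 1 of 10 (exact p = 7.29e-15). These clusters were narrower than the arm clusters that scored as high. Arm clusters within their interquartile width range (1576 to 2321.5 bp in replicate 1, 1397.25 to 1754 bp in replicate 2) were set against all 19 and all 20. Those arm clusters were also shared more often, 51.8% in replicate 1 (exact p = 0.000287) and 34.8% in replicate 2 (exact p = 0.0285). They were not matched by score, with medians of 0.54 and 0.46. In the combined list, 92.5% of all 3438 clusters under 1301 bp, on any sequence, were outside both replicate lists. Among those scoring at least 1, few overlapped a replicate list. It was 5 of 68 on unplaced and heterochromatic sequence (7.35%, 2.43 to 16.3) and 2 of 36 on the arms and chromosome 4 (5.56%, 0.68 to 18.7). At 1301 bp or more and the same score limit, 3 of 10 and 174 of 174 did. Both replicate lists began at 1301 bp, so low recovery below that width is in part built into the lists. Few reads behind the score, a candidate explanation, predicted less overlap than on arm clusters with scores as high, and both replicate lists met this. No read number entered that test, so it cannot decide for few reads. Those arm clusters were also wider, with medians of 4870 bp against 1936 bp in replicate 1 and 4191 bp against 1521 bp in replicate 2. Reads shared between repeats were not tested and stay open, and no biological explanation was tested.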
